A study of Rattus norvegicus with 14 samples.

How the data were processed

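Affymetrix Gene 1.0 ST arrays were hybridised with RNA from rat foreskin, 1 array per litter, for 7 corn oil and 7 flutamide litters. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit, and 50 ng of total RNA was amplified with the NuGEN Applause WT-Amp ST system and labelled with the Encore biotin module. Each sample pooled 2 foreskins of 1 litter, per the series' design text.

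The authors deposited a table of log2 values, 28826 probe sets by 14 samples, which the submitters' processing notes say were made with RMA. RMA corrects background, normalises between arrays and summarises probes into a probe set value; its version and the level of summary are not given in the sources used here. The log2 scale was read from the values themselves, which run from 0.669 to 13.8 with nearly equal medians in all samples. RMA shrinks differences of dim probe sets, and normalising between arrays removes any change shared by most genes. The scanner files and detection calls were not used here, so no gene was called present or absent.

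Probe sets were named with GEO's platform annotation, and symbols were updated by gene number through a RefSeq table of the GRCr8 assembly, which matched 14471 of the 14497 genes tested. Of the probe sets, 15209 had 1 gene symbol, 306 had several and 13311 had none or were not listed. Only those with 1 symbol were tested, and for the 494 genes with more than 1 probe set the brightest over all 14 samples was used. No coordinates are given, because the array's genome build is not given in the sources used here. Near-identical gene copies may share a probe set, which these values cannot separate.

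The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of gene differences are limma's standard errors. On data made from the residuals of these samples, with 200 of the 14497 genes changed, the same fit recovered on average 16.0% of 1.2-fold, 68.3% of 1.3-fold, 96.7% of 1.5-fold and 99.9% of 2-fold changes. These shares hold for that many changed genes. Where fewer genes change, the adjustment asks for a smaller p-value and fewer are recovered. In the real data Kpna2, at 1.30-fold with a limma p of 3.7e-05, had an adjusted p of 0.179.

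Before the data were examined, 31 gene lists were fixed for this tissue and treatment: androgen, oestrogen and other steroid receptor, patterning, Wnt and aryl hydrocarbon receptor genes; markers of basal and cornified epidermis, hair follicle, sebaceous gland, fibroblasts, smooth and skeletal muscle, adipocytes, endothelium, red blood cells, macrophages, mast cells, lymphocytes and neutrophils, Schwann cells, melanocytes, cartilage and bone, and urothelium; and cholesterol, cell cycle, p53, immediate early, stress, hypoxia, interferon, respiratory and ribosomal genes. The mean log2 value of each list per sample was compared with a two-sided exact permutation test over all splits of 14 samples into 7 and 7, whose smallest possible p is 0.000583, and adjusted over the lists. Intervals of list differences are 95% confidence intervals from the pooled spread between litters. A check of X- and Y-linked genes was planned, but none of its genes was among those tested.

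The rule for named genes was also fixed beforehand: the genes past the threshold, up to 12 per direction, filled by p-value to 5 per direction where fewer than 5 passed; the members with the smallest p-values in each list described, here 3; and 11 fixed genes. Predicted genes and olfactory or vomeronasal receptor genes, and with them other chemosensory receptor genes, were passed over in the first part, 2 among the higher and 1 among the lower. Lists were described by member where they concerned hormone, patterning or xenobiotic pathways or had an exact p under 0.1, a choice made after the values were seen. The alternatives were other filters, summaries, scalings and models, each litter left out in turn, and a fit with the replicate number as a block. Fits without both ends of the first principal component or with the SD of each array as a covariate, and leaving out litters for lists and components, were added after the data were seen. The numbers are shared between groups but are not said to mark a shared dam, day or batch, so the planned main fit did not treat them as pairs. Same-numbered samples deviated together with correlations from -0.07 to 0.15, over 0.1 in 1 of 7 pairs. This does not exclude a batch shared by number.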

Results

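Foreskin gene expression was measured on postnatal day 5 in Sprague Dawley rat pups whose mothers had been dosed by oral gavage on gestational days 16 to 20. The dams received either corn oil, the vehicle, or 5 mg/kg/day flutamide, an antiandrogen drug. Each group held 7 litters, and each sample was RNA pooled from 2 foreskins of 1 litter, so the litter was the replicate. Affymetrix Gene 1.0 ST arrays gave 1 log2 value per probe set and sample, and 14497 genes were compared. The medians of the samples lay within 0.073 of each other, and correlations between samples ran from 0.984 to 0.992 across genes. The number of arrays limits the precision, and the median standard error of a group difference was 0.07 on the log2 scale.

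The first comparison asked which genes differed in the foreskin after prenatal exposure to the antiandrogen. Snrpf, which encodes the Sm protein F of the spliceosome core, fell in the flutamide litters and was the 1 gene that passed the test. Its mean was 8.02 ± 0.09 (SD, n = 7) in corn oil and 7.56 ± 0.15 (SD, n = 7) in flutamide litters, on the log2 scale. The difference of -0.47 (SE 0.07), a 0.724-fold level, had an adjusted p of 0.0274 in limma's moderated test with Benjamini-Hochberg adjustment. All 7 flutamide litters lay below all 7 corn oil litters for this gene (probe set 10901920, NCBI gene 680737). No gene rose at an adjusted p under 0.05. The Snrpf difference stayed between -0.50 and -0.42 when each litter was left out in turn. Its limma adjusted p stayed under 0.05 only without corn oil replicate 2 or flutamide replicates 5, 6 or 7, and otherwise reached up to 0.109. It was 0.116 with the replicate number as a block, 0.0604 over all probe sets and 0.0673 without corn oil replicate 1 and flutamide replicate 7, and with the basal keratinocyte and skeletal muscle list means as covariates the difference was -0.38 with an adjusted p of 0.238.

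Differences between the groups were small for most of the 14497 genes tested. The next gene by p-value had an adjusted p of 0.179 in the limma fit. For 99.3% of genes, the 95% confidence interval of the difference excluded a change of 1.5-fold in either direction, and for 99.9% it excluded 2-fold. These shares concern array values and include dim genes, whose differences RMA shrinks, with no gene called present or absent. At an unadjusted p under 0.05 there were 1328 genes, of which 826 had higher and 502 lower values in flutamide litters, where 725 would be expected with no effect. With each sample centred on its own median, these became 668 higher and 641 lower. The groups did not overlap for 18 genes, 14 higher and 4 lower, where chance gives 0.0583% of genes, or 8.45. Probe sets with no gene name are outside these counts. Among them, 10700401 was higher in flutamide litters by 1.04 (SE 0.13), with a limma adjusted p of 0.0132 over all probe sets.

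Among genes that did not pass, those next in order with lower values in flutamide litters were Higd1b, Des, Anxa13 and Dsg4. Higd1b, a gene used as a pericyte marker, had a log2 difference of -0.38 (SE 0.07; limma adjusted p = 0.179). Des, which encodes the muscle intermediate filament desmin, had a difference of -0.34 (SE 0.07; limma adjusted p = 0.302). Both showed no overlap between the groups. Anxa13, an annexin of epithelial cells, differed by -0.36 (SE 0.08), and Dsg4, a desmosomal cadherin of the hair shaft, by -0.29 (SE 0.06).

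The 5 genes next in order with higher values in flutamide litters were Kpna2, Klk12, Slc16a8, Tgfa and Klkb1. Kpna2, an importin alpha of nuclear import, had a difference of 0.38 (SE 0.07; limma adjusted p = 0.179) on its brighter probe set, with every flutamide litter above every corn oil litter. Its other probe set, at a mean log2 value of 8.47, differed by only 0.02. Klk12, a kallikrein protease, differed by 0.38 (SE 0.08), and Slc16a8, a monocarboxylate transporter, by 0.32 (SE 0.07). Tgfa, a ligand of the epidermal growth factor receptor, differed by 0.28 (SE 0.06), and Klkb1, plasma kallikrein, by 0.42 (SE 0.10). The limma adjusted p was 0.302 for these 4 genes, for Anxa13 and for Dsg4.

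**Figure D1:**
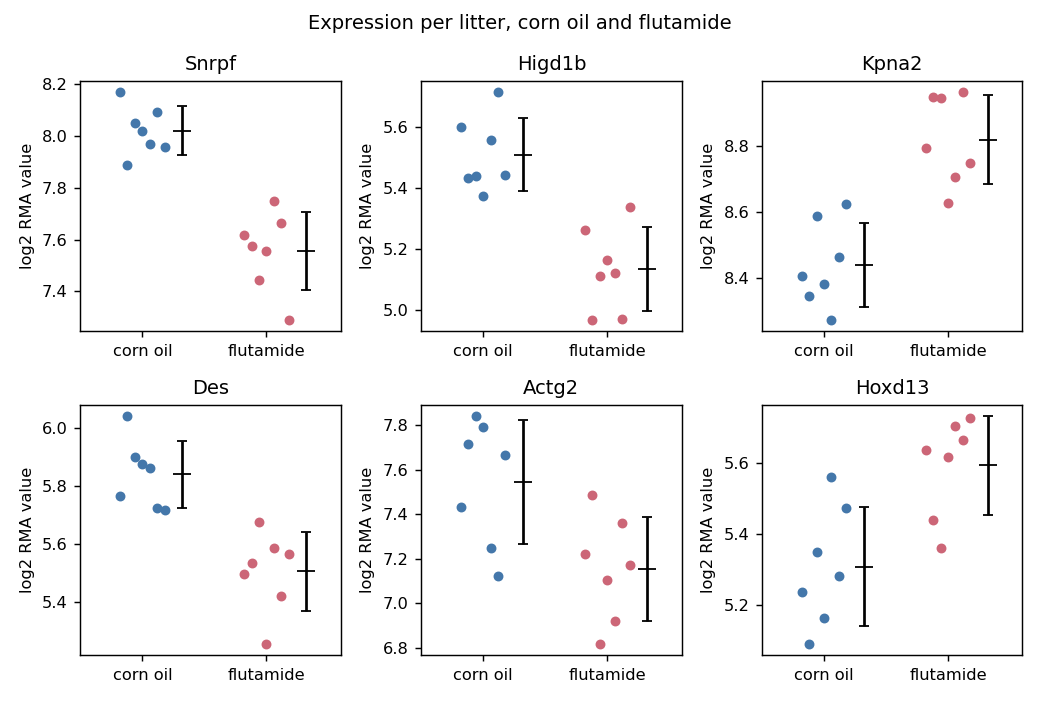
Log2 RMA value (vertical axes, each with its own range) of 6 genes in the 7 corn oil and 7 flutamide litters. Points are litters, horizontal marks are means and bars are 1 SD; Snrpf, Higd1b, Kpna2 and Des show no overlap between groups, while Actg2 and Hoxd13 do, and of these genes only Snrpf passed the test.

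The androgen list showed no difference beyond the spread between litters. Its 22 measured members, androgen targets and enzymes of androgen metabolism, had a mean log2 value of 6.36 ± 0.02 (SD, n = 7) in corn oil and 6.36 ± 0.04 (SD, n = 7) in flutamide litters. The difference was 0.003 with a 95% confidence interval from -0.03 to 0.04 (exact permutation p = 0.848, adjusted over 31 lists 0.998). None of the members passed over all genes tested, and none when adjusted over the list alone. The smallest p-values were those of Akr1c14, the rat enzyme that inactivates dihydrotestosterone, with a difference of -0.24 (SE 0.07; limma adjusted p = 0.348), and Tmprss2, an androgen-regulated protease, with 0.27 (SE 0.09; limma adjusted p = 0.368). Hsd17b6 differed by 0.15 (SE 0.07) on its brightest probe set and by 0.002 and -0.04 on its 2 others. Fkbp5, a well-known androgen and glucocorticoid target, differed by -0.11 with an interval from -0.28 to 0.07, and the growth factor gene Igf1 by -0.06 with an interval from -0.19 to 0.08. With single litters left out Fkbp5 ran from -0.15 to -0.06, and Igf1 from -0.08 to -0.02. Srd5a2 was not analysed here.

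Receptors for other steroids also gave no call. The list of oestrogen, progesterone and other steroid receptor genes differed by 0.02 (interval -0.02 to 0.06; exact permutation p = 0.302, adjusted 0.670), with 12 of 18 members above 0 and none passing over all genes or adjusted over the list alone. The list difference ran from 0.010 to 0.029 with single litters left out. Esr1, the oestrogen receptor alpha gene, differed by 0.13 (SE 0.09), Pgr, the progesterone receptor gene, by -0.05 (SE 0.11) and Nr3c1, the glucocorticoid receptor gene, by -0.10 (SE 0.06). Hsd17b2, whose enzyme oxidises oestradiol and testosterone, differed by 0.12 (SE 0.08). The list of aryl hydrocarbon receptor and xenobiotic response genes differed by -0.002 (interval -0.06 to 0.05; exact permutation p = 0.952, adjusted 0.998). Within it Cyp1a1 differed by -0.10 (SE 0.09), Cyp1b1 by -0.15 (SE 0.09), Cyp1a2 by 0.19 (SE 0.09) and Ahr itself by -0.13 (SE 0.06), none of them passing. With single litters left out Cyp1a1 ran from -0.14 to -0.05, Cyp1b1 from -0.20 to -0.09 and Esr1 from 0.10 to 0.20.

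Genes that pattern the genital tubercle and prepuce did not pass as a group, but 2 of the 24 members passed when adjusted over the list alone. Hoxd13, a homeobox gene of the distal limb and genital bud, had higher values in flutamide litters, 5.59 ± 0.14 against 5.31 ± 0.17 (SD, n = 7 each). Its difference of 0.28 (SE 0.08) had a limma p of 0.0412 adjusted over the list alone and of 0.304 over all genes. Msx2, a homeobox gene of epithelial appendages, had a difference of -0.18 (SE 0.05), with 0.0412 over the list and 0.348 over all genes. Efnb2 differed by -0.14 (SE 0.07) and Shh by -0.01 (SE 0.07). The list mean differed by 0.007 (interval -0.02 to 0.04; exact permutation p = 0.693, adjusted 0.942).

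The Wnt signalling list differed by -0.001 (interval -0.03 to 0.03; exact permutation p = 0.945, adjusted 0.998), with 13 of 27 members above 0 and none passing. The smallest p-values belonged to the secreted Dickkopf family member Dkk3 with 0.20 (SE 0.07), the ligand Wnt10b with 0.15 (SE 0.06) and the receptor Lgr5, a stem cell marker, with -0.21 (SE 0.08).

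The list of smooth muscle and pericyte genes had the largest difference of the 31 lists. Its mean was 6.82 ± 0.07 (SD, n = 7) in corn oil and 6.70 ± 0.06 (SD, n = 7) in flutamide litters, a difference of -0.12 (interval -0.20 to -0.05). Of its 14 members, 12 were below 0 and none passed over all genes, while Des and Actg2 passed when adjusted over the list alone, with limma p of 0.00147 and 0.0267. Actg2, the smooth muscle gamma actin gene, differed by -0.39 (SE 0.12) and Mylk, myosin light chain kinase, by -0.14 (SE 0.05). The exact permutation p of the list was 0.00641, and 0.190 after adjustment over the 31 lists, so the list did not pass. With limma's camera test its adjusted p was 0.000673 at a preset correlation and 0.178 with an estimated correlation. The skeletal muscle list differed by -0.05, endothelium by -0.05, dermal fibroblasts and matrix by -0.02 and mast cells by -0.07, with exact permutation p-values of 0.267, 0.162, 0.500 and 0.129. With single litters left out these differences ran from -0.078 to -0.027, -0.060 to -0.024, -0.042 to -0.0066 and -0.097 to -0.044.

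Hair follicle genes had a mean difference of -0.07 (interval -0.16 to 0.01; exact permutation p = 0.0956, adjusted 0.558), with 14 of 21 members below 0. None passed over all genes and 3 passed when adjusted over the list alone. These were Dsg4, the inner root sheath keratin gene Krt73 with a difference of -0.30 (SE 0.07), and Msx2, with list-adjusted limma p of 0.00361, 0.00361 and 0.0240. The basal keratinocyte list, by comparison, differed by -0.03 (interval -0.10 to 0.04) and the list of cornified and suprabasal epidermis by 0.01 (interval -0.05 to 0.08). Neither passed, with exact permutation p of 0.365 and 0.670, and with single litters left out they ran from -0.05 to -0.01 and from -0.004 to 0.03.

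Cholesterol biosynthesis genes had a mean of 7.12 ± 0.08 (SD, n = 7) in corn oil and 7.20 ± 0.03 (SD, n = 7) in flutamide litters. The difference of 0.08 (interval 0.01 to 0.15) had an exact permutation p of 0.0122, which became 0.190 over the 31 lists. Of the 16 members 15 were above 0, and none passed over all genes or adjusted over the list alone. Sqle, squalene epoxidase, differed by 0.17 (SE 0.07), Insig1, a regulator of sterol synthesis, by 0.19 (SE 0.08), or 0.12 without corn oil replicate 1, and Nsdhl, a sterol dehydrogenase, by 0.12 (SE 0.06). With camera, the hair follicle and cholesterol lists each had an adjusted p of 0.00942 at a preset correlation, as did oxidative phosphorylation genes, at a list difference of -0.07, which ran from -0.09 to -0.04 with single litters left out and was -0.01 without corn oil replicate 1 and flutamide replicate 7. With an estimated correlation, adjusted p = 0.652 for hair follicle, adjusted p = 0.637 for cholesterol and adjusted p = 0.724 for oxidative phosphorylation.

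The melanocyte list differed by 0.08 (interval 0.006 to 0.15; exact permutation p = 0.0367, adjusted 0.379) in these albino rats, at a low mean level of 4.61 in corn oil. Its members with the smallest p-values were the pigment genes Tyrp1 with 0.19 (SE 0.08), Slc45a2 with 0.14 (SE 0.06) and Gpr143 with 0.18 (SE 0.08). The melanocyte difference ran from 0.06 to 0.10 with single litters left out (exact permutation p up to 0.0763). It was 0.06 (exact permutation p = 0.126) without corn oil replicate 1 and flutamide replicate 7. Dim genes in general were slightly higher in flutamide litters, by a median of 0.034 in decile 2 and 0.021 in decile 3 of level. The list of cartilage and bone genes differed by 0.06 (interval -0.003 to 0.12; exact permutation p = 0.0565, adjusted 0.438). Runx2, a transcription factor of bone formation, differed by 0.21 (SE 0.09), and the matrix genes Hapln1 and Matn1 by 0.15 (SE 0.07) and 0.14 (SE 0.09), the last by 0.08 without corn oil replicate 1. The cartilage and bone difference ran from 0.04 to 0.08 with single litters left out (exact permutation p up to 0.117) and passed only without corn oil replicate 2 (adjusted 0.0361). It was 0.03 (exact permutation p = 0.208) without corn oil replicate 1 and flutamide replicate 7, the latter apart from the other flutamide litters on this list. In neither list did a member pass over all genes or adjusted over the list alone.

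The interferon response list was set apart by 1 litter. Flutamide replicate 1 had a list mean of 5.82, while the other 13 samples lay between 4.69 and 4.95. The groups differed by 0.04 with this litter (interval -0.29 to 0.37; exact permutation p = 0.998) and by -0.11 without it (exact permutation p = 0.00524, adjusted over the lists 0.163). No member of the list passed over all genes or adjusted over the list alone.

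None of the 31 lists passed the exact permutation test, 3 had an unadjusted p under 0.05, and limma's directional fry test also called 0. Fry's mixed test, which counts members moving either way, gave an adjusted p of 0.0128 for the hair follicle list. It gave 0.0128 for the smooth muscle and pericyte list as well. Differences of the lists not yet given ran from -0.04 for cell cycle and for ribosomal protein genes to 0.06 for red blood cell genes, with exact permutation p of 0.150, 0.452 and 0.286. With single litters left out these ran from -0.05 to -0.02, -0.06 to -0.01 and 0.03 to 0.08. The other differences were 0.05 for hypoxia and glycolysis, 0.03 for lymphocytes and neutrophils, 0.02 for heat shock and unfolded protein response and 0.01 for urothelium and glandular epithelium. For p53 targets the difference was 0.0004, for Schwann cells -0.002, for immediate early genes -0.003, for adipocytes -0.01, for macrophages -0.01 and for sebaceous and preputial gland lipid synthesis -0.03. Without flutamide replicate 1, which stood apart on both lists, the lymphocyte and neutrophil difference was -0.007 and that of macrophages -0.05. With single litters left out, hypoxia and glycolysis ran from 0.03 to 0.06, heat shock from 0.009 to 0.03, macrophages up to 0.02, adipocytes from -0.02 to -0.006 and sebaceous lipid synthesis from -0.04 to -0.02. In the hypoxia and glycolysis list, 1 of 18 members passed when adjusted over the list alone. This was Ldha, lactate dehydrogenase A, chosen after its values were seen, with a difference of 0.25 (SE 0.06; limma adjusted p over all genes = 0.302).

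**Figure D2:**
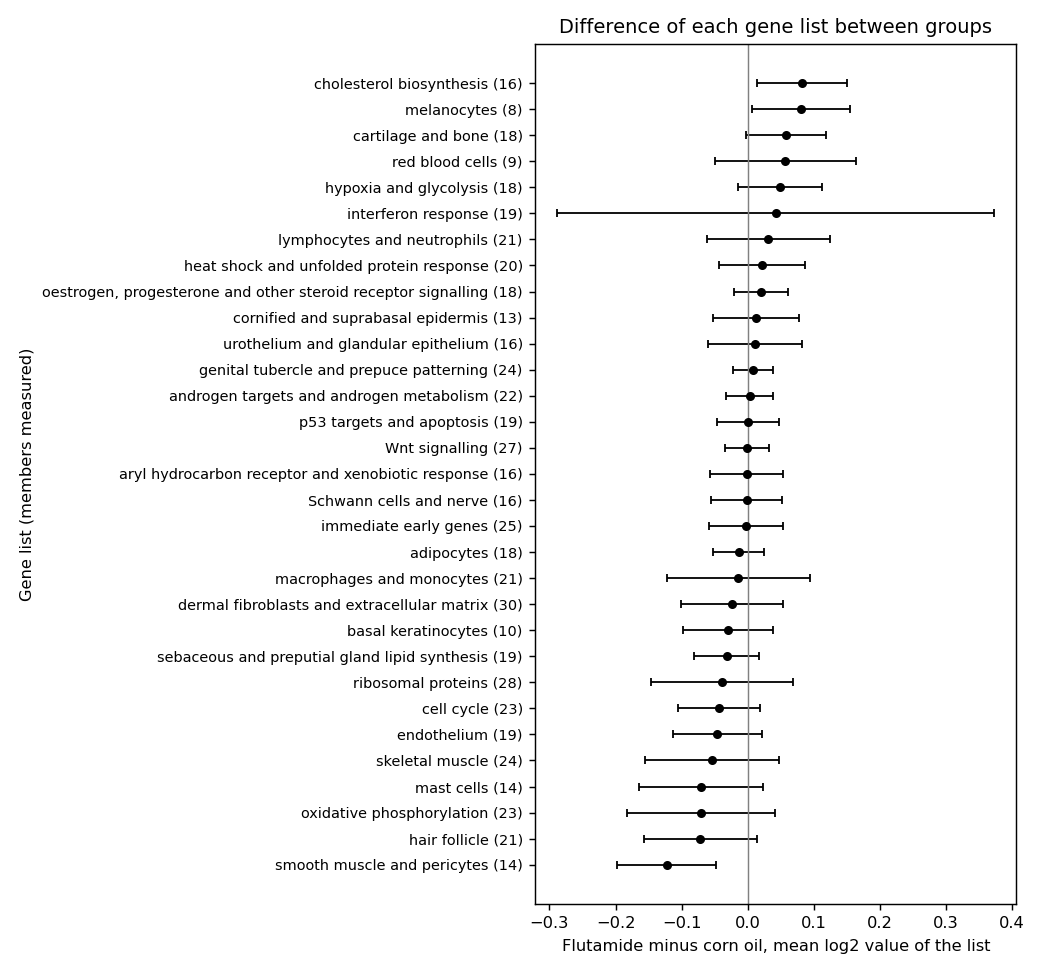
Difference between groups, flutamide minus corn oil, in the mean log2 value of each of the 31 gene lists (horizontal axis), with the number of measured members in brackets; points are differences and bars their 95% confidence intervals over 7 litters per group. The smooth muscle and pericyte list lies lowest at -0.12 and cholesterol biosynthesis highest at 0.08, and no list had an adjusted exact permutation p under 0.05.

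**Figure D3:**
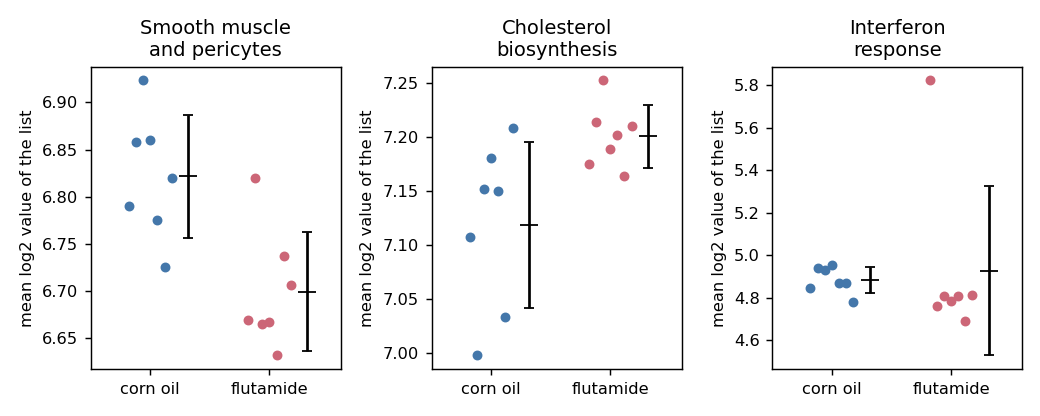
Mean log2 value (vertical axes, each with its own range) of 3 gene lists in each litter; points are litters, horizontal marks are means and bars are 1 SD. In the interferon panel the single high point is flutamide replicate 1, at 5.82.

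Seen over all genes, the groups overlapped. The first principal component held 15.7% of the variance and the second 12.4%. Group means on the first component were -4.08 ± 6.16 (SD, n = 7) for corn oil and 4.08 ± 7.26 (SD, n = 7) for flutamide litters. The exact permutation p was 0.0321, or 0.0641 after adjustment over the 2 components, so neither passed. Without corn oil replicates 1, 3 or 4, or flutamide replicate 5, the exact permutation p of the first component was 0.0589, 0.0723, 0.203 and 0.0641. Its ends were also the ends of array spread. Corn oil replicate 1 had the lowest score, -15.5, and the highest SD of its values. Flutamide replicate 7 had the highest score, 18.3, and the lowest SD, 1.48. Corn oil replicate 6, with the next lowest SD, 1.52, scored 1.72. The SD did not differ between groups beyond the spread between litters (exact permutation p = 0.266). Whether array spread underlies the group difference on this component was not tested.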

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

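The test of smooth muscle against other non-epithelial lists, both tests of the chemosensory receptor genes and both tests of flutamide replicate 1 were chosen, or had their rule for deciding changed, only after the result was seen, as was the fit with the SD of each array's values as a covariate for gene counts. For the receptor genes, the first rules counted against a shift of dim probe sets and for a change of the receptors themselves; asking for a bound beyond the spread and adding a comparison with other named genes left both undecided. A test of whether the spread of each array explains the count at an unadjusted p under 0.05 was also run, did not decide (715 higher and 483 lower genes with that covariate), and was then dropped from the patterns weighed. Of 154 groups of 7 values checked, 15 had a litter whose gap to the nearest other took more of the group's range than Dixon's 95% limit allows, where chance gives 7.7.

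Flutamide replicate 1 stood apart from the other 6 flutamide litters in its interferon response list at 5.82, macrophage and monocyte list at 6.16 and lymphocyte and neutrophil list at 5.25, and in the protease gene Klk12 at 6.89. Its interferon list was 1.04 above the mean of the other flutamide litters, 13 of 19 members were at their highest of all 14 samples, and the chemokine gene Cxcl10 was 2.80 and the antiviral gene Mx1 2.03 above those litters. The tables argue against blood mixed into the sample, since its red blood cell list differed by -0.0048 from the other flutamide litters and lay within the range of the other 13 samples. They also argue against a shift of the whole array, since the highest of 1000 sets of 19 other genes matched on level lay 0.21 above the other flutamide litters; this replaced a test on the median gene, which normalisation holds in place. An interferon response of this litter, immune cells in the tissue and handling stay open, the last untested. The macrophage list was 0.25 and the lymphocyte and neutrophil list 0.27 above the other flutamide litters. The latter list holds S100a8 and S100a9, which were 1.63 and 1.67 above those litters, so its excess does not stand for lymphocytes alone. The epithelial genes Krt16 and Il36a were 1.62 and 1.64 above those litters.

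The smooth muscle and pericyte list was lower in flutamide litters by a difference of -0.12 and missed the threshold over 31 lists. Fewer cells of every non-epithelial type cannot be told apart: the list lay below the mean of 5 other such lists, themselves at -0.039 (difference -0.083, exact permutation p = 0.0239), but allowing for its choice as the lowest the exact permutation p was 0.167. The tables argue against the spread of each array, with a difference of -0.11 left when its SD was a covariate (-0.114, permutation p = 0.0111), and against 1 deviating litter, since leaving out any litter left at least -0.105 (highest exact permutation p = 0.0128). A response of smooth muscle to flutamide, a difference in dissection and chance among the lists stay open, and the first and second were not tested.

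Chemosensory receptor genes, 1279 in number and mostly near the bottom of the range, had a mean of 3.66 ± 0.03 (SD, n = 7) in flutamide and 3.60 ± 0.06 (SD, n = 7) in corn oil litters (exact permutation p = 0.0379), and made up 160 of the 826 higher and 32 of the 502 lower genes at an unadjusted p under 0.05. Unnamed probe sets of the same level differed by 0.011 (interval -0.03 to 0.05; exact permutation p = 0.529), and the receptors exceeded them by 0.046 (exact permutation p = 0.0169). Against other named genes of the same level the excess was 0.023 (exact permutation p = 0.135). A shift of dim probe sets in general and one of the receptors cannot be told apart. Within samples the receptors exceeded the unnamed probe sets, but they did not exceed other named genes of the same level beyond the spread. The interval of the unnamed probe sets reaches most of the receptors' difference of 0.057, but it does not compare them within samples.

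Corn oil replicate 1 lay apart from the other 6 corn oil litters for Dsg4 at 5.73, Hsd17b2 at 6.34, Insig1 at 7.37 and Mylk at 6.02, and for the endothelium list at 6.69. Flutamide replicate 7 lay apart for the cartilage and bone list at 5.76, the p53 list at 6.63, the SD of its values at 1.48 and its mean over chemosensory receptor genes at 3.73. Cyp1b1 was outlying in corn oil replicate 4 at 6.76, and flutamide replicate 6 was outlying on the second principal component at 17.4.

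Among probe sets with no gene name, 10700401 was higher in flutamide litters by 1.04 (SE 0.13), a 2.06-fold level, in limma over all probe sets (adjusted p = 0.0132). Its lowest flutamide value, 5.16, lay above its highest corn oil value, 4.72.

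The grouping of the samples was compared with other splits of the same samples, 100 in all with the real one. As many genes at an unadjusted p under 0.05 as the real 1328 came up in 4 splits, with 1529 in the highest other, and as many at an adjusted p under 0.05 as the real 1 in 2 splits, with 1 in the highest other. Both shares lie under 0.05, but they do not exclude chance. Only 100 of the 3432 splits were drawn, and 3 other splits reached the first count. The second share adds little to the adjusted p of Snrpf, since the adjustment itself keeps calls rare in splits with no difference. The Snrpf call was also lost in 10 of 14 runs that left out 1 litter.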

How the results depend on the processing

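Leaving out both ends of the first principal component, the covariate for the SD of each array, and leaving out litters for lists and components were chosen after the data were seen. The number of genes at an adjusted p under 0.05, 1 as reported, was 0 with the replicate block, with tissue covariates, at a fold of at least 1.5 and without both ends of the first component. It was 2 among the 7249 brightest genes (Snrpf and Kpna2), with a trended and robust prior (Snrpf and Kpna2) and with the SD covariate (Snrpf and Higd1b), and 1328 at an unadjusted p under 0.05. Leaving out litters gave 0 to 1 genes, and without corn oil replicate 6 that gene was LOC252890, with Snrpf at a limma adjusted p of 0.0527. Over all probe sets the 1 call was the unnamed probe set.

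At an unadjusted p under 0.05, 508 genes were higher among the 10873 brightest, 276 among the 7249 brightest and 1580 over all probe sets, with 1242 lower over all probe sets and 334 lower with tissue covariates. The share higher was 62.2% as reported, 51.0% after centring on medians, 52.2% after quantile normalization, and 52.8% and 44.3% among the 10873 and 7249 brightest genes. Fewer or more genes tested account for part of these counts, though not for the share higher, and otherwise the cause was not tested. The difference between groups followed the level of the genes. Its median was 0.048 in decile 1, the dimmest genes, fell to -0.020 in decile 9 and was -0.0078 in decile 10. Snrpf was lower under every setting, at -0.50 to -0.38.

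Of the lists, 4 passed with camera's preset correlation, but none with camera's estimated correlation, where the lowest adjusted p was 0.178. The hair follicle and smooth muscle lists passed with fry's mixed test. When litters were left out, 0 to 1 passed the exact permutation test, the 1 being cartilage and bone without corn oil replicate 2. Among the 7249 brightest genes, differences reversed for patterning (-0.025), Wnt (0.0014), urothelium (-0.021), immediate early (0.00013) and interferon genes (-0.031). Without both ends of the first component they reversed for xenobiotic response (0.010), fibroblasts (0.0038), macrophages (0.026), urothelium (-0.016) and ribosomal genes (0.017), and with genes scaled to unit variance for adipocytes (0.0076) and immediate early genes (0.013). With single litters left out, 12 of the 31 lists changed direction in at least 1 run, most often p53 (9 of 14 runs), Schwann cell (6), Wnt and immediate early (5 each), androgen and xenobiotic (4 each) and urothelium genes (2), and once each patterning, cornified epidermis, macrophages, lymphocytes and interferon. These lists stayed between -0.050 and 0.047, except interferon, at -0.11 to 0.082. Pgr reversed with tissue covariates (0.019) and ran from -0.12 to 0.017 when litters were left out, and Shh from -0.052 to 0.026. The exact permutation p of the first component was 0.0801 without both its ends and 0.0157 to 0.203 when litters were left out. The cause was not tested for these, and the other 1040 gene values, and 109 list values in settings with more than 1 or no litter left out, kept direction and side of the threshold, apart from 14 settings that ended the Snrpf call and 3 that passed Kpna2 or Higd1b. Some values that kept their direction changed in size with tissue covariates. Klkb1 went from 0.42 to 0.26, Gpr143 from 0.18 to 0.05, Hapln1 from 0.15 to 0.09, Matn1 from 0.14 to 0.09 and Cyp1a2 from 0.19 to 0.10. Ahr went from -0.13 to -0.08 and Fkbp5 from -0.11 to -0.02, while Esr1 went from 0.13 to 0.23 and Igf1 from -0.06 to -0.10. None of these passed. With no detection calls, signal over background was not assessed.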

Other observations

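Genes of this paragraph were chosen after their values were seen, and none passed the test. With predicted and receptor genes set aside, the largest differences were those of Trappc2l at 0.87 (SE 0.36), Fam111a at -0.78 (SE 0.32), Krt16 at 0.63 (SE 0.27), Spopfm2l2 at -0.58 (SE 0.15), Ska2 at -0.54 (SE 0.25), Mup5 at -0.53 (SE 0.40) and Krt13 at 0.51 (SE 0.20). Among genes with smaller differences, the claudin gene Cldn17 differed by 0.45 (SE 0.11) and the defensin gene Defb2 by 0.45 (SE 0.12). For the epithelial genes Krt16, Krt13, Cldn17 and Defb2 the limma adjusted p were 0.506, 0.443, 0.302 and 0.302, and without flutamide replicate 1 the differences were 0.40, 0.57, 0.41 and 0.39. Without that litter the epithelial genes Il36a and Wfdc18 went from 0.44 to 0.20 and from 0.40 to 0.25, and Tmprss11b and Stfa2l1 from 0.49 to 0.43 and from 0.48 to 0.40. Lower values were seen for Fabp4, a lipid-binding protein gene of fat cells, at -0.43 (SE 0.16; limma adjusted p = 0.416), and for the cyclin gene Ccnb2 at -0.48 (SE 0.17; limma adjusted p = 0.368).

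One hypothesis, drawn from such epithelial genes, was that activated or mucosal epithelium may be higher in flutamide litters. A separate list of 14 such genes, written before its values were seen, differed by 0.16 (0.157, interval -0.005 to 0.32; exact permutation p = 0.0501), with 12 members above 0, so the test did not decide. The hypothesis came from the same samples, so this was not an independent test. S100a8 and S100a9 were already on the lymphocyte and neutrophil list. Among the 14 genes Sprr3 differed by 0.33 (SE 0.12), Defb4 by 0.33 (SE 0.09) and Slpi by 0.25 (SE 0.08). Leaving out litters gave 0.11 to 0.19, lowest without flutamide replicate 1. The exact permutation p was 0.0105, 0.0408, 0.0321 and 0.0367 without corn oil replicate 1 and flutamide replicates 2, 4 and 7, and over 0.05 without any other litter.

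Another hypothesis was that the genes of the spliceosome core may be lower together with Snrpf. A list of 15 other genes was used, Sm and Lsm genes together with Snrpa and Snrnp70, which encode U1 proteins outside those families. Its mean differed by -0.042 (SE 0.029, interval -0.10 to 0.02, exact permutation p = 0.165), with 5 members above 0. Its Sm genes Snrpb, Snrpd1 and Snrpn differed by 0.10 (SE 0.06), 0.02 and 0.05, and Snrpd2 and Snrpg by -0.14 and -0.09. Lsm6 was at -0.15 (SE 0.06). The Sm genes Snrpd3 and Snrpe were not on the list. By the bound set beforehand, a difference under 0.1, this argues against the hypothesis for the mean of this list. The value lies within the bound by more than its standard error and far from the -0.47 of Snrpf. A stricter rule tried after the value was seen, with the whole interval inside the bound, would leave the hypothesis undecided, and a smaller shared difference is not excluded. The Sm core alone was not tested.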
